A study of Mus musculus with 9 samples.

How the data were processed

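RNA of mouse F9 embryonal carcinoma cells was measured on 9 oligonucleotide arrays, 3 for each of 3 groups: cells given the ethanol vehicle, retinoic acid (RA) at 0.5 µM, or the histone deacetylase inhibitor trichostatin A (TSA) at 0.07 µM, each for 24 h. Per the labels, total RNA was treated with DNase and cleaned on columns before hybridisation at a core facility. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

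The deposited table holds a linear ratio per probe set and array. In all 12488 probe sets the vehicle arrays averaged 1 within 1e-05, so the authors' values are ratios to the vehicle mean of each probe set. Brightness is not recoverable from them, and a large ratio can rest on a dim vehicle signal. The steps between scanner and ratio are not given in the sources used here. Array medians ran from 0.819 to 1.01, a range of 1.24 times. Because this was under 1.5, the ratios were used as deposited, without further scaling.

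The 66 control probe sets were left out, which left 12422. A platform annotation gave 1 gene symbol for 10833 of them, several for 396 and none for 1193. Symbols were updated through Entrez IDs with a RefSeq table of the GRCm38.p6 assembly, and 16 probe sets had an ID outside that table. No gene was named from a probe set with several symbols. The log2 values of a gene's probe sets were averaged, giving 8251 genes, of which 2073 had several probe sets. In RA against vehicle, 41 of the 46 such genes with any changed probe set had another that did not pass; the counts were 97 of 113 for TSA against vehicle and 111 of 125 for RA against TSA. In 1 gene, 6330403K07Rik, probe sets passed in opposite directions, -2.724 and 2.652 in TSA and 2.884 and -1.945 in RA against TSA, and their average did not pass.

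Values were analysed as log2(ratio + 0.05), so fold changes are on that scale and understate changes of low values. One limma fit (version 3.58.1, R 4.3.3) over all 9 arrays gave the 3 comparisons, with 6 residual degrees of freedom. Probe sets and genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. For 23 gene lists, limma's camera with a preset correlation of 0.01 compared members with other genes, adjusted over the 23 lists, and was repeated with an estimated correlation. The lists, groups, thresholds, alternatives and naming rule were fixed before the data were examined. The naming rule took the 10 largest rises and falls per treatment among genes past the threshold whose arrays did not overlap, the 3 smallest adjusted p of each list, the 5 largest differences each way between treatments, up to 10 genes changed in both, and a fixed set of marker genes. Rarb and H1f0 from that set had no probe set with 1 symbol. Genes named outside this rule were chosen after their values were seen: in RA Meis1, Nrip1, Hoxb5, Hoxb9, Utf1, Tbx3 and Sox7, and in TSA Cdkn2b, Nsdhl, Phlda2, Ndn, Bhlhe40, Crabp1, Aldh1a2, Dazl, Thy1, Col5a1, Col1a2, Col3a1, Fn1, Tdgf1, Utf1, Hsp90b1, Id1, Wnt6, Sfrp2 and Lgals1, with 6330403K07Rik, Vim, Sparc and Postn.

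The design had assumed brightness, and 3 steps were replaced after the values proved to be ratios. A filter on the lowest 30% by mean would remove genes that fell, so no filter was used. Choosing the probe set with the highest mean would favour rises, so probe sets were averaged. A variance trend on the mean was not fitted, because the mean of ratios follows the change itself. The 3 steps as first designed were run as alternatives. With the trend, limma with Benjamini-Hochberg adjustment gave 111 changed probe sets for RA, 352 for TSA and 509 for RA against TSA.

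The procedure was tested on simulated data, 20 sets with 200 changed among 12422 probe sets. For RA against vehicle it recovered 14.3% of 2-fold rises, 14.5% of 2-fold falls, 56.8% of 4-fold rises and 79.1% of 8-fold rises. False calls made up 5.89% of calls for RA and 6% for TSA. With the trend, false calls were 0.772% and 1.73%, and for RA 13.4% of 2-fold rises and 2.42% of 2-fold falls were recovered. The number of arrays limits the precision. The simulated arrays had independent errors, with the same spread in all groups for each probe set. The vehicle arrays varied most and may not have scattered independently, so the false call rates may differ in the data.

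Alternatives were other pseudocounts (0.01 and 0.1), quantile normalisation, centring on array medians, filters, other rules for the probe set of a gene, fits on the 6 arrays compared, a replicate block and leaving out each array. Array weights and leaving out both arrays with the highest 18S signal, vehicle replicate 3 and RA replicate 3, were chosen after seeing the data. Vehicle replicate 1 had the next highest 18S signal (a median of 0.538) and stayed in.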

Results

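Expression was compared between F9 cells, a mouse embryonal carcinoma line that differentiates toward endoderm when given retinoic acid, after 24 h with vehicle, 0.5 µM RA or 0.07 µM TSA, with 3 arrays per group. TSA inhibits histone deacetylases. The design asks which transcripts each compound changes and which respond to both. The vehicle arrays varied most, with a median SD of 0.413 on the log2 scale, against 0.311 for RA and 0.260 for TSA. The median probe set was lower than vehicle by a log2 change of -0.12 in RA and -0.17 in TSA. Centring the arrays moved these medians to 0.035 and 0.029, and the fold changes below are not corrected for these shifts, while camera compares each list with the other genes. The median signal of 18S rRNA control probe sets was 2.4 times the vehicle mean on vehicle replicate 3, 0.961 on RA replicate 3, 0.538 on vehicle replicate 1, 0.073 on vehicle replicate 2 and 0.0723 or less on the other RA and TSA arrays. Hybridisation spike-in controls had medians of 0.895 to 1.05 on the vehicle arrays, 0.557 to 0.717 on the TSA arrays and 0.616, 0.412 and 1.1 on RA replicates 1, 2 and 3.

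RA strongly raised genes of the retinoid response. Stra8, a retinoid-induced gene of meiotic germ cells, reached 224 ± 14.9 times the vehicle mean (SD, n = 3). Cyp26a1, which degrades RA, reached 61.5 ± 15 times, and Crabp2, which carries RA in the cell, 44.8 ± 14.8 times. The rises continued with Hoxb4 (log2 change 4.98), Calcoco2 (4.85), the endoderm factor Foxa1 (4.70), Crygc (4.03), Zfp703 (4.0), Foxq1 (3.94) and the retinol transporter Stra6 (3.94). The largest falls among genes past the threshold were Cyp2j6 (-2.78), the fatty acid transporter Slc27a2 (-2.71), Mmp10 (-2.44), the growth regulator Myc (-2.39), Inhbb (-2.39), Tdgf1 (-2.37), Myh3 (-2.34), Sh3gl2 (-2.22), Foxd3 (-1.99) and Runx1t1 (-1.98). Of 9 fits that each leave out 1 array, the calls of Sh3gl2, Mmp10, Inhbb and Foxd3 held in 2, 3, 3 and 4. Those of Cyp2j6 and Slc27a2 held in 5 and 6. Stra8 had an adjusted p of 0.000168 and Myc one of 0.00168 (limma, Benjamini-Hochberg). The calls of Stra8, Crabp2 and Foxa1 each held in 21 of 22 settings, where the same test gave adjusted p up to 0.193, 0.0523 and 0.0709.

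In all, 169 of 12422 probe sets changed with RA, 116 higher and 53 lower, or 150 of 8251 genes, 98 higher and 52 lower. All 169 had RA and vehicle arrays that did not overlap, as had 17% of all probe sets, where chance gives 10%. Centring on array medians gave 148 higher and 37 lower, and quantile normalisation 74 and 13. With the variance trend of the first design, 98 were higher and only 13 lower. The count was 98 without both arrays with the highest 18S signal, 61 from the 6 arrays alone and 74 without vehicle replicate 2. It was 54, 64 and 85 without RA replicates 1, 2 and 3, and 109 without TSA replicate 1.

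Of 26 measured genes in the list of retinoid metabolism and known RA targets, 11 rose, and adjusted over the list alone 13 rose and 1 fell. They included Cdx1 (3.85), Meis1 (3.37) and Nrip1 (1.81). The list had a camera adjusted p of 4.63e-18, and of 0.00126 with an estimated correlation. Of 31 Hox genes, which pattern the body axis, 11 rose and none fell, with 12 rises adjusted over the list alone. Besides Hoxb4 they included Hoxb5 (3.78), Hoxb1 (3.68), Hoxb9 (3.63) and Hoxa5 (3.07). The camera adjusted p was 2.36e-14, and 0.0744 with an estimated correlation.

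Among 31 genes of the undifferentiated state, 6 fell and 2 rose in RA; adjusted over the list alone, 15 fell and 3 rose. Zfp42 (-1.69), Utf1 (-1.74) and Tcl1 (-1.53) fell, while Lefty1 (2.05) and Tbx3 (1.49) rose. The core factors Pou5f1 (-0.92, adjusted p = 0.211) and Nanog (-0.66, adjusted p = 0.189) did not pass limma's test with Benjamini-Hochberg adjustment. The list had a camera adjusted p of 1.51e-05, and 0.0656 with an estimated correlation. It was 0.386 with the 30% filter and 0.563 with the 50% filter, which act on the mean ratio and take out genes that fell.

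Of 24 genes of basement membrane and parietal endoderm, 3 rose in RA, Plat (2.56), Serpinh1 (1.18) and Lama1 (1.13), with 8 adjusted over the list alone; leaving out 1 array, the calls of Lama1 and Plat held in 1 and 3 of 9 fits. This list had a camera adjusted p of 1.51e-05, and 0.0687 with an estimated correlation. Of 32 genes of primitive and visceral endoderm, Foxa1, Gata6 (1.93) and Sox7 (1.21) rose and Fst (-1.94) fell, with the same counts adjusted over the list alone. The calls of Sox7 and Gata6 held in 2 and 5 of 9 fits without 1 array. The probe sets of Gata6 changed by 3.75, 1.65 and 0.38, and only the first passed. The mean of this endoderm list on vehicle replicate 3 (0.353) lay near those on the RA arrays (0.390, 0.482 and 0.466), with vehicle replicate 1 at -0.352. The camera adjusted p of the list was 0.00174, and 0.519 with an estimated correlation. It was 0.287 without vehicle replicate 1. Gata4 (0.12), Sox17 (0.11) and Lamb1 (-0.33) did not pass. The imprinted genes Sgce (1.31) and Plagl1 (1.85) rose, 2 of 23, or 4 adjusted over the list alone, with a camera adjusted p of 0.0275, and 0.115 with an estimated correlation. This imprinted call held in 14 of 22 settings. The camera adjusted p was 0.0804 after centring and 0.0909 without both arrays with the highest 18S signal. It was 0.083, 0.087 and 0.0703 without vehicle replicates 1 and 3 and RA replicate 1, and reached 0.273 with the 50% filter. The other 17 lists had camera adjusted p from 0.0812 to 0.594.

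**Figure D1:**
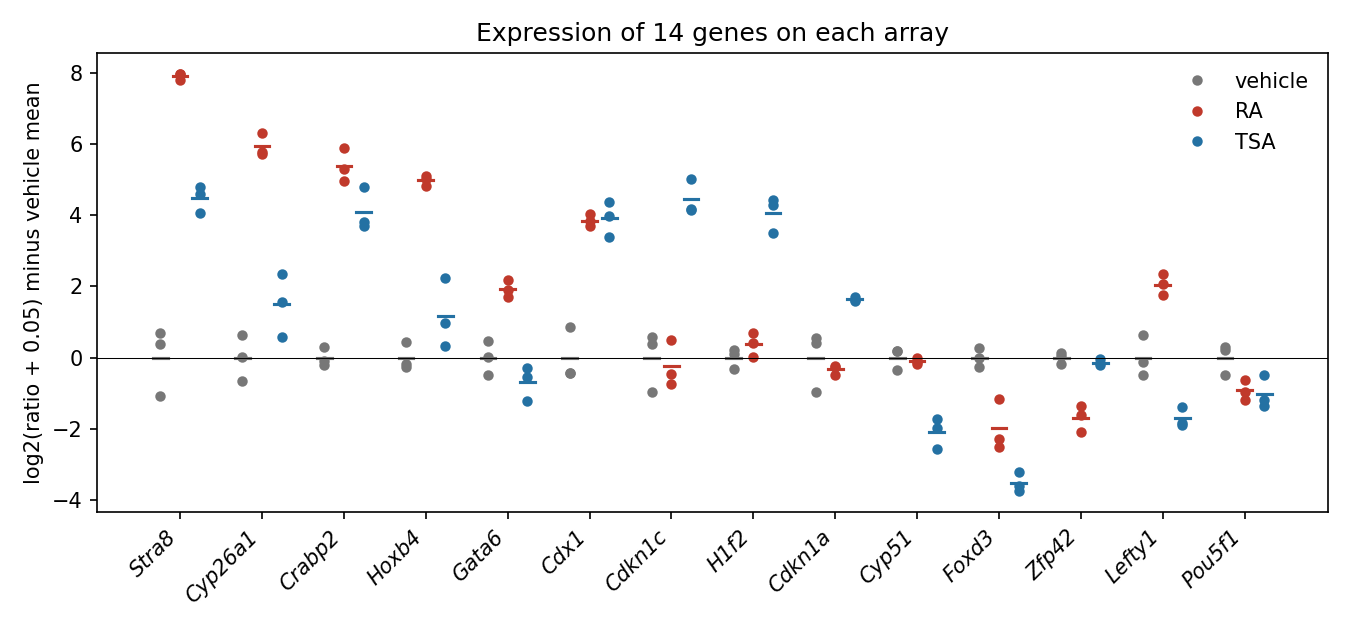
Each point is 1 array's log2(ratio + 0.05) minus the vehicle mean, for 14 genes, and bars are group means of 3 arrays. Stra8 averaged 7.91 in RA and 4.49 in TSA, while Cdkn1c averaged -0.23 in RA and 4.45 in TSA.

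In TSA, Muc3, a mucin, reached 36.2 ± 23.4 times the vehicle mean (SD, n = 3), Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, 21.6 ± 7.75 times, and Stra8 21.2 ± 5.21 times. Rab3b (4.28), S100a6 (4.12), Crabp2 (4.10), the linker histone H1f2 (4.07), the chromatin remodeller Smarca2 (4.05), Mlf1 (3.99) and the cohesin gene Stag3 (3.97) followed on the log2 scale. The largest falls among genes past the threshold were Foxd3 (-3.53), Inhbb (-3.32), Pkdcc (-2.37), Spout1 (-2.30), Vegfc (-2.12), Cyp51 (-2.09), Tgfbr2 (-2.06), Sema5b (-2.02), Zfp101 (-1.94) and Fkbp9 (-1.94). H1f2 had an adjusted p of 0.000709 and Foxd3 one of 0.00188 (limma, Benjamini-Hochberg). The TSA calls of Stra8 and Crabp2 each held in 21 of 22 settings, where the same test gave adjusted p up to 0.334 and 0.0713. Those of Smarca2 and Mlf1 each held in 17 of 22. Of the falls, Foxd3 and Inhbb each held in 19 of 20 settings, with adjusted p up to 0.378 and 0.464 by the same test. Tgfbr2 and Sema5b each held in 16 of 20 and Zfp101 in 15 of 20.

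In all, 432 probe sets changed with TSA, 274 higher and 158 lower, or 371 genes, 224 higher and 147 lower. The TSA and vehicle arrays of all 432 did not overlap, against 26.3% of all probe sets and 10% by chance. Centring gave 379 higher and 82 lower, and quantile normalisation 84 and 24. With the variance trend of the first design, 266 were higher and 86 lower. The count was 400 without both arrays with the highest 18S signal, 168 from the 6 arrays alone and 183 without vehicle replicate 2. It was 276 without RA replicate 2, and 193, 107 and 162 without TSA replicates 1, 2 and 3.

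Of 27 genes known to respond to deacetylase inhibitors, 8 rose and 1 fell; adjusted over the list alone, 14 rose and 3 fell. They included Clu (3.53), Gsn (3.5), and the cyclin-dependent kinase inhibitors Cdkn2b (3.08) and Cdkn1a (1.64), the last held in 2 of 9 fits without 1 array. For this list the camera adjusted p was 5.62e-09, and 0.124 with an estimated correlation. Of 16 genes of cholesterol synthesis and uptake, 8 fell and none rose, with 12 falls adjusted over the list alone. Besides Cyp51, Msmo1 (-1.76), Nsdhl (-1.36) and Idi1 (-1.31) encode enzymes of the pathway. These falls gave a camera adjusted p of 8.83e-09, and 0.124 with an estimated correlation; it was 0.797 with the 50% filter, which takes out genes that fell. Of 40 cell cycle and replication genes, E2f1 (-0.99), Rrm2 (-0.94) and Mcm4 (-0.81) fell and none rose, with 17 falls adjusted over the list alone; without 1 array these calls held in 4, 2 and 1 of 9 fits. By camera the adjusted p was 3.05e-08, and 0.169 with an estimated correlation.

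Of 23 imprinted genes, 5 rose, Cdkn1c, Mest (2.42), Plagl1 (2.20), Phlda2 (1.74) and Ndn (1.20); adjusted over the list alone, 9 rose and 2 fell. Their camera adjusted p was 5.94e-06, and 0.0383 with an estimated correlation. In the retinoid list 6 rose and Bhlhe40 (-1.48) fell, or 9 and 1 adjusted over the list alone, with Cdx1 (3.91), Crabp1 (2.07) and Aldh1a2 (1.63) among the rises; the call of Bhlhe40 held in 3 of 9 fits without 1 array. Its camera adjusted p was 0.000325, and 0.0528 with an estimated correlation; it was 0.102 with the 50% filter. Of 18 trophoblast genes, Tfap2c (3.26), Esx1 (2.21), Phlda2 and Plac8 (1.70) rose, or 5 and 1 fall adjusted over the list alone. The camera adjusted p was 0.00591, and 0.114 with an estimated correlation. Of 15 germline genes, Stra8, Tex19.1 (3.06), Dazl (1.45) and Ddx4 (1.06) rose, or 4 and 1 fall adjusted over the list alone. The call of Dazl held in 3 of 9 fits without 1 array, and neither of its probe sets passed singly (0.037 and 2.87). The list mean on vehicle replicate 3 (0.503) lay above those on TSA replicates 1 and 2 (0.427 and 0.492), with vehicle replicate 2 at -0.545. The camera adjusted p was 0.0119, and 0.124 with an estimated correlation; centring the arrays (0.0572) and leaving out vehicle replicate 2 (0.0891) ended this call.

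Of 24 markers of fibroblasts, muscle and feeder cells, Cnn1 (3.18), Thy1 (3.00), Ccn2 (2.77), Col1a1 (2.45) and Col5a1 (0.94) rose in TSA, with 7 adjusted over the list alone. Of the Col1a1 probe sets, at 0.59 and 4.31, only the second passed. Other collagen and matrix genes of these cell types did not pass, among them Col1a2 (0.054), Col3a1 (-0.31) and Fn1 (-0.18). The camera adjusted p was 0.000131, and 0.124 with an estimated correlation. With the preset correlation this call held in 22 of 22 settings. The list mean was 0.432 on vehicle replicate 3, against -0.186 and -0.247 on vehicle replicates 1 and 2. On TSA replicates 1, 2 and 3 it was 0.691, 0.536 and 0.927. In the list of the undifferentiated state 5 genes fell, Foxd3, Lefty1 (-1.71), Tdgf1 (-1.53), Utf1 (-1.34) and Gdf3 (-1.28), or 13 and 1 rise adjusted over the list alone; without 1 array the calls of Tdgf1 and Utf1 held in 3 and 2 of 9 fits. Its camera adjusted p was 0.0154, and 0.124 with an estimated correlation. The list call held in 17 of 22 settings, with a camera adjusted p of 0.0755 without vehicle replicate 1, 0.0698 with the variance trend and 0.783 with the 50% filter. With the 30% filter the list turned from lower to higher, with a camera adjusted p of 0.85. Pou5f1 (-1.02, adjusted p = 0.0988) and Nanog (-0.39, adjusted p = 0.318) did not pass limma's test with Benjamini-Hochberg adjustment.

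Smaller list shifts in TSA were p53 targets (2 rises of 20, Perp at 1.36 and Plk2 at 1.16, which held in 2 of 9 fits without 1 array; 3 rises and 1 fall adjusted over the list alone), linker and replacement histones (2 rises of 10, H1f2 and H1f10 at 1.57; 2 rises and 1 fall over the list alone) and neural genes (2 rises of 27, Mapt at 2.06 and Syt1 at 1.77; 3 over the list alone). Their camera adjusted p were 0.0195, 0.0386 and 0.0446, and 0.190, 0.124 and 0.124 with an estimated correlation. The p53 call was lost without vehicle replicate 3 (camera adjusted p = 0.0696) and without both arrays with the highest 18S signal (0.0663). Leaving out each array in turn, the histone call held in 5 of 9 fits and the neural call in 3 of 9, with adjusted p up to 0.0694 and 0.128, both without vehicle replicate 1. Centring also ended them (0.0572 and 0.0946). None of 16 housekeeping genes passed singly, with 1 rise and 4 falls adjusted over the list alone. That list was lower by camera, with an adjusted p of 0.0329, and 0.346 with an estimated correlation. The housekeeping call held in 15 of 22 settings, and the adjusted p was 0.0824, 0.0524 and 0.0506 without vehicle replicates 1, 2 and 3, 0.0622 without TSA replicate 1, and up to 0.783 with the 50% filter. The other 10 lists had camera adjusted p from 0.139 to 0.904.

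**Figure D2:**
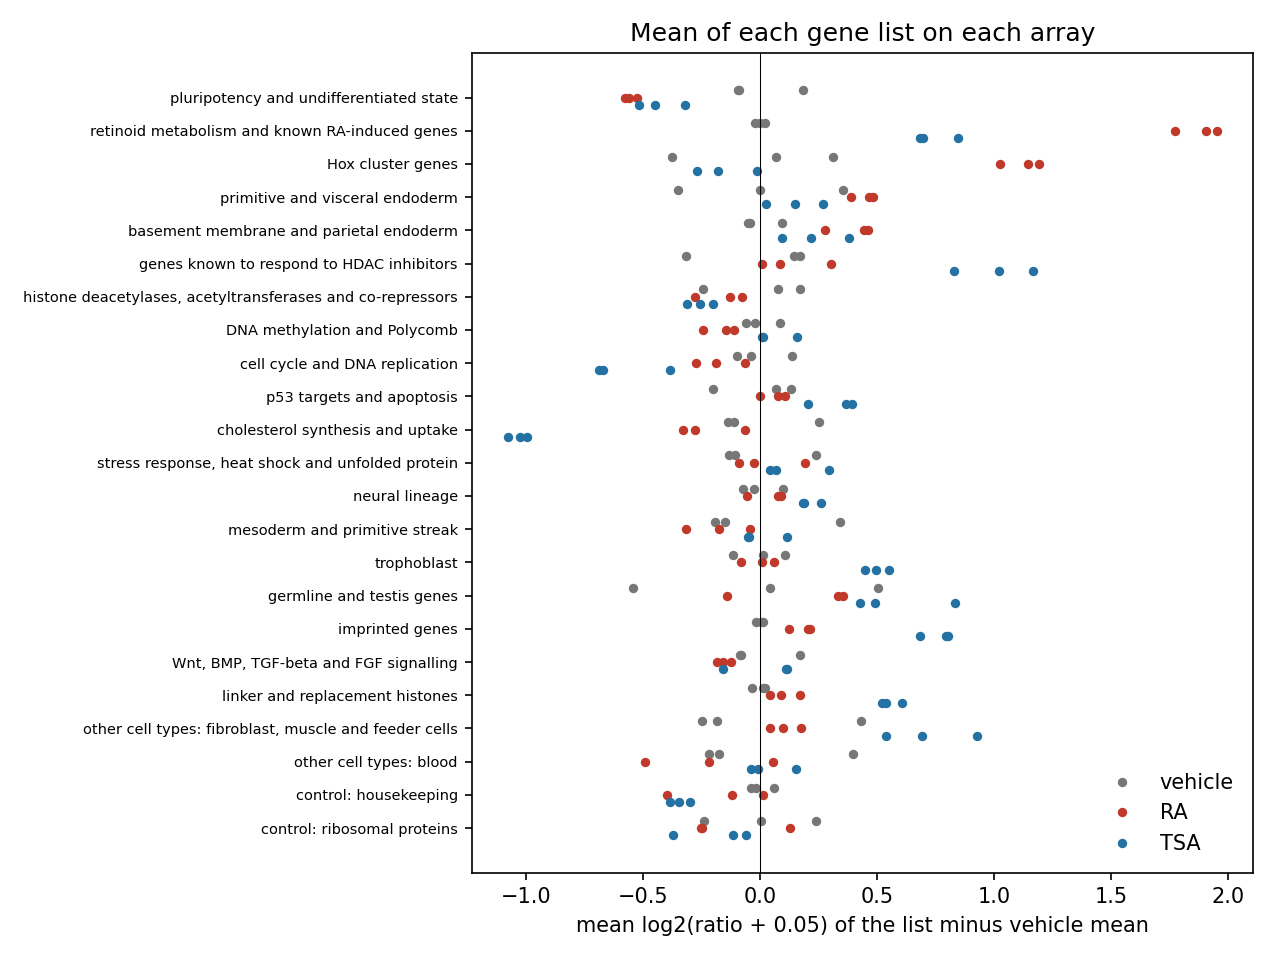
Each point is the mean log2(ratio + 0.05) of a gene list on 1 array, minus the mean of the vehicle arrays, for 23 lists. The retinoid list had a mean log2 change of 1.88 in RA and 0.74 in TSA, and the cholesterol list -0.23 in RA and -1.03 in TSA.

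The treatments were also compared directly. RA exceeded TSA most for Foxa1 (5.42), Foxq1 (4.70), Cyp26a1 (4.44), Stra6 (4.41) and Hoxb9 (4.28), and TSA exceeded RA most for Muc3 (-5.19), Cdkn1c (-4.68), Tgfb1 (-4.59), Thy1 (-4.35) and Coch (-4.32). Gata6 (2.62), Zfp42 (-1.55), Myc (-1.86), Col4a1 (1.59) and Cdkn1a (-1.96) differed too, with Col4a1 and Cdkn1a held in 4 and 3 of 9 fits without 1 array. In all, 486 probe sets differed, 211 higher in RA and 275 higher in TSA, or 412 genes, 182 and 230. All 486 had arrays that did not overlap, against 27.3% of all probe sets and 10% by chance. The count was 152 after quantile normalisation, 238, 207 and 271 without RA replicates 1, 2 and 3, and 205, 167 and 225 without TSA replicates 1, 2 and 3.

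The Hox list was higher in RA than in TSA, with 10 genes past the test and 14 adjusted over the list alone, and a camera adjusted p of 2.42e-11, or 0.174 with an estimated correlation. The retinoid list had 11 genes higher and 1 lower in RA, or 15 and 5 adjusted over the list alone, with a camera adjusted p of 1.65e-05, or 0.0448 with an estimated correlation. The cholesterol list was higher in RA, with 6 genes, or 11 adjusted over the list alone, and a camera adjusted p of 3.58e-08, or 0.233 with an estimated correlation. The cell cycle list was also higher, with 1 gene each way, or 4 higher and 1 lower adjusted over the list alone, and a camera adjusted p of 1.62e-05, or 0.331 with an estimated correlation. Higher in TSA were the deacetylase inhibitor list (12 genes, with 2 higher in RA; 12 and 3 adjusted over the list alone), the fibroblast list (4; 6 over the list alone) and the imprinted list (3; 5 over the list alone, with 2 the other way). Their camera adjusted p were 0.000164, 0.0163 and 0.0192, and 0.331, 0.331 and 0.174 with an estimated correlation. Without TSA replicate 3 the fibroblast and imprinted calls were lost (0.0669 and 0.0521), and quantile normalisation ended the imprinted call (0.135). The filters ended the cholesterol call (0.0584 and 0.624). The other 16 lists had camera adjusted p from 0.0755 to 0.904.

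Some genes changed with both compounds. Cdx1 rose by 3.85 in RA and 3.91 in TSA, and Msx2 by 3.52 and 3.53. Stra8, Crabp2, Calcoco2, Prph, Ackr3, Sema3e, Plat and Fbp1 passed as higher in both, and Foxd3, Inhbb and Tdgf1 as lower in both. Lefty1, a Nodal antagonist, rose by 2.05 in RA and changed by -1.71 in TSA, and Cyp2s1 went the other way, -1.82 in RA and 1.49 in TSA. In RA, the calls of Fbp1 and Plat held in 1 and 3 of 9 fits without 1 array and those of Inhbb and Foxd3 in 3 and 4, while in TSA the call of Tdgf1 held in 3. In all, 46 probe sets were higher in both, 14 lower in both and 2 opposite. Centring on array medians gave 65 higher and 6 lower in both, and quantile normalisation 19 and 3. The fits on the 6 arrays gave 12 higher and 2 lower, the variance trend 27 and 0, and the filters, which take out genes that fell, 54 and 0 or 63 and 0. Of the single arrays, leaving out RA replicate 1 gave the fewest, 15 and 2. The same-direction count was 21 and 28 without RA replicates 2 and 3 and 25 without vehicle replicate 2. It was 31, 23 and 25 without TSA replicates 1, 2 and 3, and 36 without both arrays with the highest 18S signal. Simulated unchanged groups against the same vehicle arrays gave 0 in each class, and independent lists would share 2.56, 0.674 and 2.65. With no effect simulated, few probe sets are expected to pass in either treatment. The simulated 0 therefore does not measure what error of the shared vehicle arrays adds to real changes. Across probe sets, which are not independent replicates, the log2 changes correlated at 0.430, against 0.498 in the simulation, and their covariance was 0.177 against 0.0878. Part of the overlap may come from the shared vehicle arrays, of which there are too few to split.

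**Figure D3:**
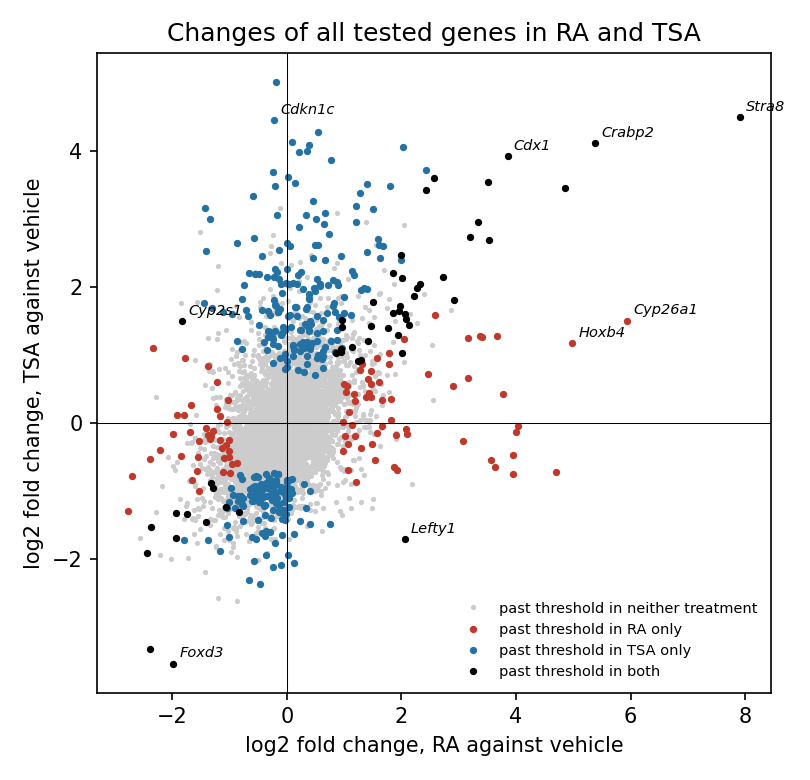
Each point is 1 of 8251 genes, with the log2 fold change against vehicle in RA on the horizontal and in TSA on the vertical axis, coloured by the comparisons in which it passed the threshold. Stra8 lies at 7.91 and 4.49, and Lefty1 at 2.05 and -1.71.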

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

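The tests of the array axis, the fibroblast list and the shared vehicle arrays were chosen after their results were seen; the splits of the arrays were planned. Lefty1 and Cyp2s1 passed the test in opposite directions in RA and TSA. The direct difference, RA minus TSA, was 3.76 for Lefty1 and -3.32 for Cyp2s1, with adjusted p of 0.000439 and 0.00036 (limma, Benjamini-Hochberg). Both were picked for passing in opposite directions, which makes a large difference expected, and independent lists would give 2.65 such probe sets against the 2 seen. Outside the tested probe sets, a control probe set named for mouse B2 averaged 1.10 times the vehicle mean in TSA, with each TSA array above each vehicle array. Another B2 control went the other way, from 0.664 to 0.735 on the TSA arrays and from 0.917 to 1.07 on the vehicle arrays. The 66 control probe sets were searched for rises only, and chance can give such a rise among so many. Falls were not searched for and could be larger. A control named for mouse B1 ran from 0.335 to 0.528 on the TSA arrays and 0.410 to 0.606 on the RA arrays, against 0.957 to 1.08 on the vehicle arrays.

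The vehicle arrays may not have scattered independently. Vehicle replicate 2 was the middle of the 3 in 57.2% of probe sets, where chance gives 33.3% for arrays of equal spread. An estimate of its own variance, from squared median absolute deviations of pairwise differences, came out at -0.109. Such deviations need not add up where noise differs among probe sets, so the sign alone is no proof of dependence. The same estimate was 0.359 for vehicle replicate 1 and 0.541 for vehicle replicate 3. With such unequal spread the share of 57.2% is no proof of dependence either. Vehicle replicate 2 was not the exact average of the other vehicle arrays on the ratio scale, since only 5.43% of its values lay within 0.01 of 1. The shares were 2.25% and 2% for vehicle replicates 1 and 3. An average taken on another scale or before scaling would not be caught by this test. A difference shared between groups may contribute, as vehicle replicate 3 minus 1 correlated at 0.3305 across probe sets with RA replicate 3 minus 1 and at 0.201 and 0.247 with TSA replicate 3 minus 1 and 3 minus 2, and so may background, since control probe sets for bacterial and yeast sequence had a median of 1.40 on vehicle replicate 3, the highest of the 9 arrays. The origin of either stays open, and no biological explanation was tested.

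The rise of fibroblast markers in TSA could come from such cells, from expression in F9 cells or in part from the difference between vehicle arrays. The 6 abundant transcripts Col1a2, Col3a1, Fn1, Vim, Sparc and Postn had a median log2 change of -0.0917, below what a large share of such cells would give if F9 cells express little of them. Their level in vehicle is not in ratios, so a small share behind a high baseline cannot be told apart from a change in the F9 cells.

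For the 60 probe sets changed the same way in both treatments, simulations with no effect and the vehicle arrays' own spread gave at most 0 by chance error of the shared vehicle arrays. These simulations assume independent arrays, which the vehicle arrays may not be. With no effect simulated, few probe sets are expected to pass in either treatment, whatever the vehicle error. The part that may come from the vehicle arrays therefore stays open. Of 100 drawn splits of the 9 arrays, 1 gave as many, the real one, and the highest other gave 24. Such splits mix the treatments, so they only test whether the groups differ at all. They cannot tell how many of the shared calls come from the shared vehicle arrays.

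The 3 comparisons allow only 10 splits of 6 arrays each, too few for a share under 0.05; in each, 1 split, the real one, gave the highest count. For RA against vehicle the real split gave 169 probe sets and the highest other 1, for TSA against vehicle 432 and 1, and for RA against TSA 486 and 2. For gene lists the real splits gave 6, 13 and 7, and the highest others 5, 10 and 5.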

How the results depend on the processing

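Of 168 calls of named genes, 77 held under all settings run for them and 102 without each array in turn; none turned direction. Of 24 calls of genes named after their values were seen, 3 held under all settings. Of 26 list calls, 12 held under all settings with the preset correlation, and with an estimated correlation 1 list passed in each comparison. The list of the undifferentiated state in TSA turned from lower to higher (median 0.028) without the lowest 30% by mean log2, a filter that by construction takes out genes that fell. Using no filter and no variance trend, both planned as alternatives, became the main setting. The counts below are for RA, TSA, RA against TSA and the same-direction overlap, against 169, 432, 486 and 60. Leaving out each array in turn gave 54 to 209, 107 to 494, 167 to 624 and 17 to 71, with vehicle replicate 2 and TSA replicate 2 ending the most named calls (44 and 49). Quantile normalisation gave 87, 108, 152 and 22; it forces the narrow vehicle ratios onto the others' distribution. Fits on the 6 arrays compared gave 61, 168, 480 and 14. The variance trend gave 111 for RA and 27 for the overlap. Leaving out both arrays with the highest 18S signal, chosen after seeing the data, gave 98 and 36, and the cause was not tested. An adjusted p under 0.01 left 47, 95 and 125. Array weights, also chosen after seeing the data, gave 2196, 4494, 943 and 1251, which are not usable counts: the weights stopped before convergence and put 21.4 on vehicle replicate 2 against 0.377 and 0.247 on the other vehicle arrays; the cause was not tested. Replicate numbers paired the samples at most in part. All pairs of number 3 correlated (vehicle and RA 0.289, vehicle and TSA 0.237, RA and TSA 0.190), as did vehicle and RA of number 1 (0.2485). Same-number correlations ran from -0.0317 to 0.289, and 4 of 9 were over 0.1. Some pairs of different number were over 0.1 too, such as vehicle replicate 1 and TSA replicate 2 (0.171). An array correlated best with its own number in 10 of 18 cases. With the replicate block the counts were 141, 438, 455 and 48, and the lists past the test 6, 11 and 8; the histone and neural lists in TSA no longer passed (adjusted p = 0.0736 and 0.0644). Signal over background is unknown, so the data cannot say which large ratios rest on dim vehicle signal.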

Other observations

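Genes of stress and growth factor signalling, lists that did not shift as a whole, held single changes in TSA. The heat shock genes Hspa1b (2.88) and Hspa1a (2.17) and the oxidoreductase Nqo1 (1.33) rose, and the chaperone Hsp90b1 (-0.84) fell, out of 27 stress genes; leaving out 1 array, the calls of Hspa1a and Hsp90b1 held in 4 and 1 of 9 fits. Tgfb1 (3.15), Id3 (2.05), Id1 (1.26) and Wnt6 (1.20) rose and Inhbb, Fst (-1.70) and Sfrp2 (-0.99) fell, out of 38 signalling genes. Of 22 genes for deacetylases, acetyltransferases and co-repressors, Kat2b (-1.68) and Mbd3 (-1.08) fell, while Hdac1 (0.064) did not pass. In RA, 1 signalling gene rose, Smad6 (1.46), and 3 fell, Bmp4 (-1.42), Fst (-1.94) and Inhbb, or 3 and 8 adjusted over the list alone. Of 27 neural genes in RA, Irx3 (2.08) and Syt1 (1.51) rose and none fell, or 4 rises and 1 fall adjusted over the list alone. The RA calls of Smad6 and Syt1 each held in 5 of 9 fits without 1 array. In TSA the lists of basement membrane and of primitive endoderm had medians (-0.094 and -0.032) and means (0.23 and 0.15) of opposite sign, and neither passed. Single genes did: Plat (3.60), Lgals1 (1.40), Lama1 (1.11) and Agrn (1.00) rose, 4 of 24 basement membrane genes with no fall, and in primitive endoderm Krt19 (1.70) rose and Fst fell. Of the Krt19 probe sets, at -0.44 and 3.83, only the second passed. The calls of Lgals1 and Lama1 held in 1 and 3 of 9 fits without 1 array.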
